A study of Homo sapiens with 8 samples.

How the data were processed

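RNA sequencing of MDA-MB-231 cells was used, in 8 libraries: 2 each of WT, SUN2KO, Kashlid and LBD. Per the labels, total RNA came from 10000000 cells per sample, libraries were made with the NEBNext Ultra kit, and reads were paired-end on a NovaSeq instrument. Per the submitters' processing notes, the authors trimmed reads with Trim Galore, aligned them to hg19 with STAR 2.7.1a, used bedtools 2.24.0, and counted reads per gene with HTSeq. The count values are the deposited raw reads per gene, 25369 genes in 8 libraries. The annotation version and the strand setting are not given in the sources used here, so genes that overlap and close paralogs may share reads.

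The authors also deposited 3 tables of comparisons with WT, which per the submitters' processing notes come from DESeq2 and which carry no column names. The log2 fold changes in the authors' deposited tables were identified by their correlation of 0.999 with values recomputed from the counts. The p-values deposited by the authors were identified in the same way, since applying Benjamini-Hochberg to one column gave the adjusted p-value column. The 12 unnamed columns per library were not used here. The authors' values serve only as a check beside the values computed here.

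Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, the filterByExpr filter (14016 genes kept), and the quasi-likelihood test with 1 term per group over all 8 libraries, leaving 4 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Log2 fold changes are given with the SE of the fit, and CPM with the SD of 2 libraries. Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation, and with fry. Of 22 lists fixed before the data were examined, 1 (mitochondrially encoded transcripts) had no measured member. The count table had 0 entries naming no gene.

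Genes were named by a rule also fixed before the data were examined: SUN2, the 10 largest changes each way against WT and the 3 largest each way otherwise. They had to pass the test at a mean of at least 5 CPM, and loci without a product name were left out. From each list up to 4 passing members were named in order of size, or where none passed up to 2 with the smallest p. Of these, 1 list and 3 list members are not reported here. Genes at 0 to 3 counts in a group are given as counts with a bound or a counting interval.

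Depth was 17115114 and 17779388 counts in WT, 18814795 and 18662262 in SUN2KO, 17041108 and 16851763 in Kashlid, and 17146119 and 16570099 in LBD. The steps were tested on simulated data made from the SUN2KO and WT libraries (13800 genes, 200 changed). The edgeR test recovered 78% of genes changed 1.5-fold and 90% of those changed 2-fold, with 13 false calls of 181. DESeq2 1.42.0 made 159 calls there, 3 of them false.

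Regional shifts were measured as medians over 5 Mb windows with at least 15 genes, against 1000 shuffles of gene positions. Alternatives planned were median-ratio factors, library size only, no filter, a stricter filter (5 CPM in 2 libraries), DESeq2, a fit of the 2 groups alone, a replicate block, leaving out each library, and a 2-fold limit. The window offset and the list tests against SUN2KO were chosen after seeing the data.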

Results

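The series profiled MDA-MB-231 cells, an established triple-negative human breast cancer line of mesenchymal appearance, by RNA sequencing. Its subject is SUN2, a protein of the inner nuclear membrane that forms LINC complexes with nesprins and so ties the nuclear lamina to the cytoskeleton. There were 8 libraries in 4 groups of 2: unmodified cells (WT), cells with SUN2 knocked out (SUN2KO), cells with a SUN2 lacking residues 569 to 585 (Kashlid), and cells with a SUN2 lacking residues 1 to 139 (LBD). Per the series design, the first truncation was made to break the link to Nesprin-2G and the second to break the link to the lamins. The labels do not say whether the truncated proteins were made in SUN2KO or WT cells, nor how they were introduced. Total counts lay between 16570099 and 18814795 per library, and 14016 of 25369 genes passed the filter on low counts. The labels do not say that the 2 replicates of a group came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

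SUN2 (chromosome 22, 39130719 to 39151467 on hg19) was examined first, because it checks the labels. Its level was 82.8 ± 1.30 CPM (counts scaled to library size, SD, n = 2) in WT, 28.0 ± 3.29 in SUN2KO, 36.3 ± 1.28 in Kashlid and 33.6 ± 1.49 in LBD. The raw counts were 1408 and 1441 in the WT libraries, 474 and 564 in SUN2KO, 643 and 603 in Kashlid, and 562 and 579 in LBD. Against WT the log2 fold changes were -1.56 ± 0.08 (SE) in SUN2KO, -1.19 ± 0.08 in Kashlid and -1.30 ± 0.08 in LBD, with adjusted p = 1.01e-11, 2.28e-10 and 9.22e-11 (edgeR's quasi-likelihood test, Benjamini-Hochberg). SUN2 transcript thus stood at 33.8% of the WT level in SUN2KO, 43.8% in Kashlid and 40.5% in LBD. Kashlid was above SUN2KO by 0.37 ± 0.09 (adjusted p = 0.00384, and 0.125 without SUN2KO replicate 1), and LBD by 0.26 ± 0.09, at the threshold (adjusted p = 0.0501). The latter passed with median-ratio factors (0.0467), library size only (0.0356), no filter (0.0341), a stricter filter (0.0474) and the replicate as a block (0.0384), but not in DESeq2 (0.109). It ranged from 0.0228 without SUN2KO replicate 2 to 0.491 without SUN2KO replicate 1. The authors' deposited tables give -1.56, -1.19 and -1.30 for the same 3 comparisons with WT. All 3 lines thus had less SUN2 transcript than WT. Counts per gene do not show whether a transcript holds the deleted part, and they do not show loss of SUN2 protein in SUN2KO.

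**Figure D1:**
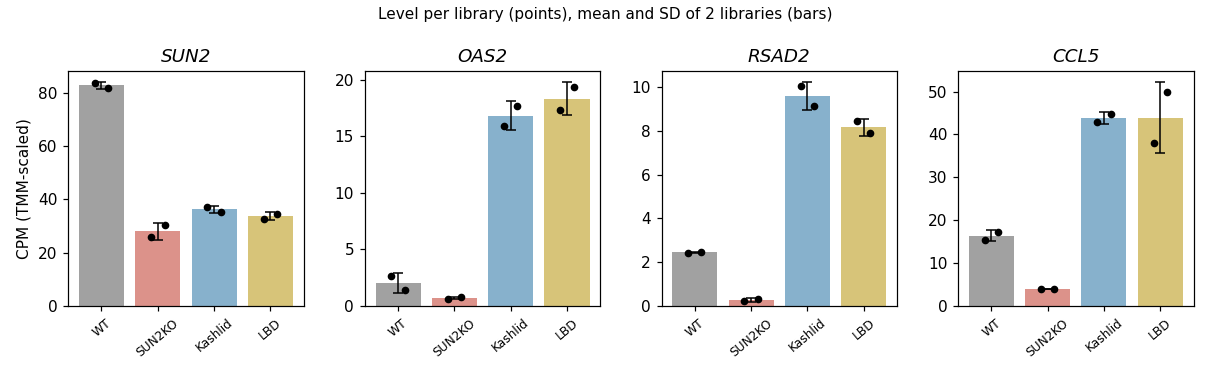
Levels of SUN2, OAS2, RSAD2 and CCL5 in CPM on linear axes from 0, with 1 point per library and bars for the mean and SD of the 2 libraries of a group. SUN2 was at 82.8 CPM in WT and between 28.0 and 36.3 in the other groups, while OAS2, RSAD2 and CCL5 were lowest in SUN2KO and highest in the Kashlid and LBD libraries.

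Comparing SUN2KO with WT asks how the line labelled as a SUN2 knockout differs. Among genes at a mean of at least 5 CPM, the deepest losses were in STC1, a secreted glycoprotein hormone (chromosome 8, 23699434 to 23712320), and TUSC3, a subunit of the oligosaccharyltransferase of the endoplasmic reticulum (chromosome 8, 15397596 to 15624158). STC1 fell 84.6-fold, from 50.8 ± 8.31 to 0.592 ± 0.607 CPM (SD, n = 2), and TUSC3 fell 34.5-fold, from 58.8 ± 6.33 to 1.70 ± 0.504 CPM. STC1 had 3 and 19 counts in the 2 SUN2KO libraries, and its log2 fold change was -5.62 without SUN2KO replicate 1 and -8.23 without replicate 2, so its depth is uncertain. AKR1C2, an aldo-keto reductase of steroid metabolism (chromosome 10, 5029968 to 5060225), rose 19.9-fold from 1.08 ± 0.240 to 21.5 ± 2.20 CPM. Its near-identical paralogs may share reads with it, so that value is uncertain. EGR1, an immediate early transcription factor, rose 8.01-fold, and PTGS1, the constitutive cyclooxygenase, rose 5.35-fold to 120.3 ± 1.36 CPM.

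Among the other genes with the largest increases were TC2N (3.27 ± 0.15), SRPX2 (3.16 ± 0.19), RNF125 (3.11 ± 0.25), ATP8A1 (2.66 ± 0.20), SYTL4 (2.66 ± 0.19), ZNF300 (2.43 ± 0.13) and COL5A3 (2.30 ± 0.29), as log2 fold change ± SE, with adjusted p of at most 3.15e-06. RNF125 is a ubiquitin ligase and ATP8A1 a phospholipid flippase. Large decreases were found in RSAD2 (-3.14 ± 0.37), KATNAL2 (-2.63 ± 0.20), OLFM1 (-2.42 ± 0.18), TNFAIP3 (-2.14 ± 0.15), CCL5 (-2.09 ± 0.16), ACSL1 (-2.02 ± 0.11), GNG11 (-1.97 ± 0.07) and NPR3 (-1.96 ± 0.17), with adjusted p of at most 1.06e-06. RSAD2 encodes the antiviral protein viperin, TNFAIP3 the NF-kB inhibitor A20 and CCL5 a chemokine. In all, 5137 genes changed, 2455 higher and 2682 lower in SUN2KO, and 630 of them by at least 2-fold. DESeq2 called 4044 genes. The authors' deposited results gave 3732 genes an adjusted p under 0.05, of which 3690 were also called here, all in the same direction.

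The unfolded protein and ATF4 list and the matrix list fell. Of 32 measured genes of the unfolded protein and ATF4 response, 0 rose, 18 fell and 14 did not pass (0 and 20 adjusted over the list alone), with a median log2 fold change of -0.37 (camera adjusted p = 1.9e-10, and 0.025 with an estimated correlation). They included the chaperones HSP90B1 (-0.89 ± 0.04) and HSPA5 (-0.68 ± 0.05) and their partners DNAJC3 (-1.12 ± 0.06) and PDIA4 (-0.80 ± 0.05), with adjusted p of at most 1.01e-09. Among 37 collagens and matrix glycoproteins, 7 rose, 18 fell and 12 did not pass (8 and 19 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 8.33e-08, and 0.025 with an estimated correlation). Fibronectin, FN1, fell 2.8-fold from 822 ± 37.9 to 293 ± 2.23 CPM, and LUM (-1.72 ± 0.08), COL5A1 (-1.29 ± 0.06) and THBS1 (-1.14 ± 0.10) fell as well (adjusted p of at most 3.75e-08). In the list of integrins and focal adhesion genes (32 measured), 1 rose, 14 fell and 17 did not pass (1 and 15 adjusted over the list alone), around a median of -0.14 (camera adjusted p = 6.87e-05, and 0.0586 with an estimated correlation). The integrin subunits ITGB8 (-0.93 ± 0.20), ITGB1 (-0.78 ± 0.05) and ITGA1 (-0.66 ± 0.06) fell, ITGB1 to 541 ± 28.1 CPM, as did the adaptor BCAR1 (-0.57 ± 0.07) (adjusted p of at most 0.000821). Cholesterol synthesis genes also fell: of 24 measured, 1 rose, 15 fell and 8 did not pass (1 and 15 adjusted over the list alone), median -0.25 (camera adjusted p = 6e-05, and 0.361 with an estimated correlation). LSS (-0.91 ± 0.08), PMVK (-0.83 ± 0.09) and IDI1 (-0.63 ± 0.09) were among those that fell (adjusted p of at most 7.51e-06).

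Epithelial genes rose. Of 28 measured genes for epithelial junctions and keratins, 16 rose, 2 fell and 10 did not pass (16 and 3 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 5.25e-10, and 0.025 with an estimated correlation). The protease inhibitor SPINT1, the tight junction protein CLDN7, the adhesion molecule EPCAM and keratin KRT15 changed most, by 1.78 ± 0.17, 1.67 ± 0.12, 1.34 ± 0.20 and 1.22 ± 0.27 (adjusted p of at most 0.00128). The 22 mesenchymal and EMT factors went both ways: 4 rose, 9 fell and 9 did not pass (4 and 11 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.199). The semaphorin receptor NRP2 rose 4.91-fold and the cadherin gene CDH4 (1.30 ± 0.35) rose, whereas TGFBI (-1.12 ± 0.07) and PDGFRB (-0.88 ± 0.14) fell (adjusted p of at most 0.00648). Cytosolic ribosomal protein genes, a marker list for RNA quality, rose slightly: of 49, 35 rose, 2 fell and 12 did not pass (36 and 3 adjusted over the list alone), median 0.18 (camera adjusted p = 1.33e-08, and 0.361 with an estimated correlation). RPS13 (0.55 ± 0.05), RPL12 (0.50 ± 0.04), RPL38 (0.48 ± 0.05) and RPS18 (0.42 ± 0.04) rose most, and pseudogene copies may share their reads.

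The lists closest to the question of nuclear force showed smaller or mixed changes. Of 26 genes of the LINC complex and nuclear envelope, 8 rose, 5 fell and 13 did not pass (8 and 5 adjusted over the list alone), median 0.04 (camera adjusted p = 0.93). Besides SUN2, the nesprin genes SYNE3 (0.86 ± 0.28) and SYNE2 (0.45 ± 0.06) rose and TMEM201 (-0.40 ± 0.09) fell, with adjusted p = 0.0209, 3.7e-06 and 0.00115. In the YAP/TAZ target list (22 measured), 1 rose, 5 fell and 16 did not pass (1 and 5 adjusted over the list alone), median -0.10 (camera adjusted p = 0.214). CYR61 (-0.53 ± 0.11), NT5E (-0.51 ± 0.12), DOCK5 (-0.50 ± 0.06) and CRIM1 (-0.44 ± 0.07) were among those that changed. For SRF/MRTF targets (23 measured), 2 rose, 9 fell and 12 did not pass (2 and 9 adjusted over the list alone), median -0.09 (camera adjusted p = 0.199, and 0.0131 with fry). TGFB1I1 (-0.99 ± 0.15) and CALD1 (-0.82 ± 0.05) fell and ACTG2 (1.39 ± 0.33) rose (adjusted p = 2.46e-05, 9.13e-11 and 0.00212). Immediate early genes were split: of 24, 4 rose, 5 fell and 15 did not pass (4 and 5 adjusted over the list alone), median 0.01 (camera adjusted p = 0.906). EGR1 and DUSP5 (0.86 ± 0.22) rose while KLF6 (-0.86 ± 0.11) and DUSP4 (-0.85 ± 0.09) fell (adjusted p of at most 0.0043).

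No common direction was found for innate immune genes. The type I interferon list had 39 measured members, of which 7 rose, 7 fell and 25 did not pass (7 and 7 adjusted over the list alone), median 0.03 and mean -0.12 (camera adjusted p = 0.848). RSAD2 (-3.14 ± 0.37), OAS2 (-1.58 ± 0.35) and DDX60 (-0.91 ± 0.10) fell and SAMD9 (0.83 ± 0.08) rose (adjusted p of at most 0.00111). For NF-kB cytokines and chemokines (23 measured), 5 rose, 8 fell and 10 did not pass (5 and 9 adjusted over the list alone), median -0.18 (camera adjusted p = 0.214), with TNFAIP3 and CCL5 given above. CXCL10 had 1 count in SUN2KO and 16 in WT, a ratio of 17.2 with a 95% counting interval of 2.68 to 723. In the matrix protease list (33 measured), 6 rose, 9 fell and 18 did not pass (6 and 10 adjusted over the list alone), median -0.09 (camera adjusted p = 0.0903). MMP16 had 5 counts in SUN2KO and 256 in WT (-5.71 ± 0.44), and PLAU (-1.50 ± 0.32) and SERPINE2 (-1.35 ± 0.07) fell while ADAM12 (1.22 ± 0.11) rose (adjusted p of at most 0.00101). Proliferation genes (45 measured) had 3 higher, 13 lower and 29 not passing (3 and 14 adjusted over the list alone), median -0.06 (camera adjusted p = 0.331). E2F1 (-0.57 ± 0.07), HMMR (-0.45 ± 0.07) and MCM10 (-0.40 ± 0.08) fell and MKI67 (0.42 ± 0.04) rose.

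Stress lists other than the unfolded protein response were mixed. For p53 and DNA damage genes (28 measured), 4 rose, 8 fell and 16 did not pass (4 and 8 adjusted over the list alone), median -0.02 (camera adjusted p = 0.394). GDF15 (-0.92 ± 0.13) and CDKN1A (-0.49 ± 0.08) fell (adjusted p = 1.26e-05 and 4.64e-05), and TNFRSF10C, with 0 counts in SUN2KO against 21 in WT, was at least 7.54-fold lower (taking 3 counts over the group as the floor). Of 34 hypoxia and glycolysis genes, 7 rose, 12 fell and 15 did not pass (8 and 14 adjusted over the list alone), median -0.18 (camera adjusted p = 0.331). The largest were in ANKRD37 (-1.32 ± 0.39), EGLN3 (-0.83 ± 0.22), MXI1 (0.75 ± 0.10) and BNIP3L (-0.74 ± 0.11). Of 18 heat shock genes, 4 rose, 3 fell and 11 did not pass (4 and 3 adjusted over the list alone), median 0.10 (camera adjusted p = 0.669). HSP90AA1 (0.40 ± 0.05) rose and HSPA4L (-0.53 ± 0.07) fell. The 2 lists of markers of other cells did not pass camera. Of 11 luminal breast markers, 4 rose, 3 fell and 4 did not pass (4 and 3 adjusted over the list alone), median 0.44 with a mean of -0.30 (camera adjusted p = 0.265, and 0.025 with fry). MLPH (-2.54 ± 0.28), FOXA1 (0.70 ± 0.13) and KRT8 (0.66 ± 0.04) were among those that changed. Of 7 HEK293-type markers, chosen because HEK293T cells were grown in the same study, 1 rose, 1 fell and 5 did not pass (1 and 1 adjusted over the list alone), median 0.08 (camera adjusted p = 0.936). LIN28B had 0 counts in WT and 28 in SUN2KO, at least 8.66-fold higher, and TUBB2B (-0.76 ± 0.17) fell.

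The 20 genes named for their size kept their call without any 1 library, in DESeq2 and with the window medians described next taken out (the window offset). Some list members named above lost their call in a setting, with adjusted p in brackets: SYNE3 (0.0549 in DESeq2, 0.205 without WT replicate 2, 0.0806 without SUN2KO replicate 1, 0.058 without SUN2KO replicate 2 and 0.071 with the window offset), NT5E (0.112 without WT replicate 2 and 0.0564 without SUN2KO replicate 2), ANKRD37 (0.0902 without WT replicate 2, 0.123 without SUN2KO replicate 1 and 0.145 with the window offset) and EGLN3 (0.0922 without WT replicate 2 and 0.0862 without SUN2KO replicate 1). So did DUSP5 (0.0674 in DESeq2, 0.0529 without WT replicate 1 and 0.109 with the window offset) and CDH4 (0.0503 without SUN2KO replicate 1), and CXCL10 (0.0797 without SUN2KO replicate 2) and TNFRSF10C (0.134 in DESeq2). With the window offset, DOCK5 was at adjusted p = 0.0918 and ITGB8 at 0.0724. In the same setting MKI67 turned to -0.27 (adjusted p = 7.74e-05) and MCM10 to 0.12 (adjusted p = 0.295).

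Neighbouring genes shifted together in all 3 comparisons with WT. The genome was divided into 5 Mb windows on hg19, and 341 windows held at least 15 tested genes. The SD of the window medians of log2 fold change was 0.193 for SUN2KO, 0.197 for Kashlid and 0.188 for LBD against WT, where 1000 shuffles of gene positions gave at most 0.0825, 0.0995 and 0.0871 (permutation p = 0.001 in each, the smallest that 1000 shuffles can give, one-sided). The window at 125 to 130 Mb of chromosome 10 was higher by 0.693, 0.76 and 0.705 in SUN2KO, Kashlid and LBD. That at 10 to 15 Mb was lower (-0.52, -0.58 and -0.55). Each window at 95 to 130 Mb of chromosome 10 was higher in all 3. Those at 5 to 30 Mb and on chromosomes 8 and 21 were lower. Others varied in sign. Window medians of the 3 comparisons, which share the WT libraries, correlated across windows at r = 0.922, 0.918 and 0.951. Against SUN2KO the SD was 0.0606 for Kashlid and 0.0613 for LBD, and between LBD and Kashlid 0.0430. These also exceeded every shuffle, by less, as the shuffles gave at most 0.0577, 0.0530 and 0.0419 (permutation p = 0.001 in each). There were 0 windows beyond 0.3 in these comparisons and 48, 44 and 41 beyond it against WT. With each window's median taken out as an offset, an alternative chosen after seeing the data, 3817, 5356 and 4498 genes changed, and 62.3%, 72.5% and 68.5% of the original calls were still made.

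**Figure D2:**
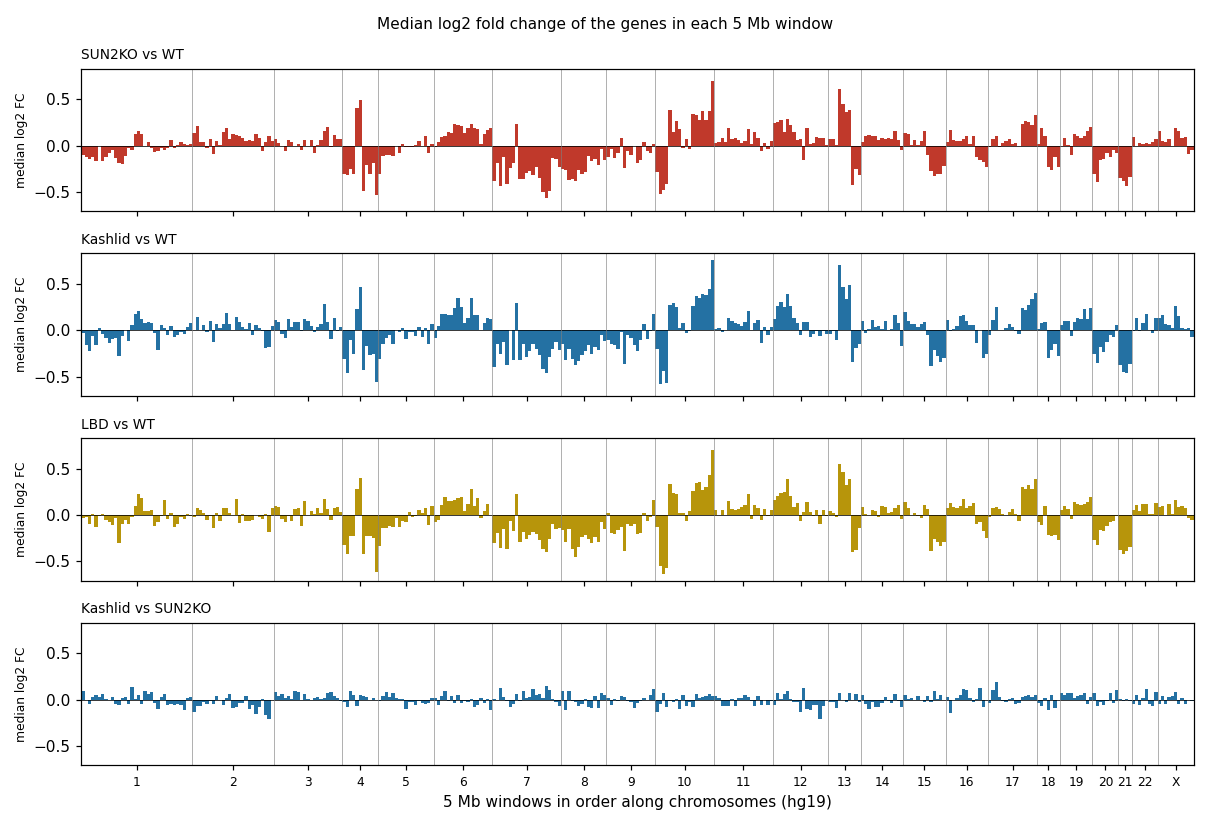
Median log2 fold change of the tested genes in each 5 Mb window, in order along the chromosomes, for the 3 comparisons with WT and for Kashlid against SUN2KO. The windows rise and fall at the same places in the comparisons with WT (SD 0.193, 0.197 and 0.188) and stay near 0 in Kashlid against SUN2KO (SD 0.0606).

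Comparing Kashlid with WT asks how the line with the truncation meant to detach SUN2 from Nesprin-2G differs. TUSC3 fell 33-fold to 1.78 ± 0.471 CPM (SD, n = 2), close to its level in SUN2KO. COL5A3, a fibrillar collagen (chromosome 19, 10070237 to 10121147), rose 19.3-fold from 0.581 ± 0.0186 to 11.4 ± 0.0490 CPM. The inducible cyclooxygenase PTGS2 (chromosome 1, 186640944 to 186649559) rose 8.82-fold from 36.4 ± 0.888 to 321 ± 72.4 CPM, and the receptor NOTCH3 (chromosome 19, 15270444 to 15311792) rose 9.56-fold to 45.3 ± 3.76 CPM. DKK1, a secreted Wnt antagonist, fell 6.09-fold from 35.3 ± 0.0171 to 5.80 ± 0.265 CPM.

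Other large increases were in AKR1C2 (3.83 ± 0.19), RNF125 (3.55 ± 0.24), TC2N (3.48 ± 0.15), SYTL4 (3.20 ± 0.19) and EGR1 (3.11 ± 0.23), with adjusted p of at most 1.21e-09. RPPH1 and RMRP, the RNA parts of RNase P and RNase MRP, had fitted changes of 6.07 ± 1.40 and 4.50 ± 1.16 (adjusted p = 0.00137 and 0.00347) that rested on 1 library. RPPH1 had 6 counts in Kashlid replicate 1 and 744 in replicate 2, and RMRP had 7 and 535. LBD showed the same split, with 4 and 170 counts of RPPH1 and 8 and 180 of RMRP. Replicate 2 was also the higher one in WT (2 and 9 counts of RPPH1, 7 and 17 of RMRP) and SUN2KO (4 and 13, 4 and 16). Without Kashlid replicate 2 the values were 0.12 (adjusted p = 0.964) and -0.77 (adjusted p = 0.699), and RMRP also missed the threshold in DESeq2 (adjusted p = 0.0589). Large decreases were found in OLFM1 (-3.24 ± 0.20), KATNAL2 (-3.12 ± 0.21), PZP (-3.03 ± 0.38), NEXN (-2.77 ± 0.15), MYLK3 (-2.71 ± 0.22), GPNMB (-2.48 ± 0.21), DNER (-2.32 ± 0.16) and QPRT (-2.10 ± 0.17), with adjusted p of at most 1.87e-06. MYLK3 encodes a myosin light chain kinase. PZP was at -2.36 without WT replicate 1. In total 6232 genes changed, 3047 higher and 3185 lower, 918 of them by at least 2-fold, and DESeq2 called 5096. With library size only, 3526 were higher and 2780 lower. The authors' deposited results had 4071 genes with an adjusted p under 0.05, of which 4066 were also called here, all in the same direction.

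Interferon-stimulated genes rose together in Kashlid. Of 39 measured genes of the type I interferon response, 28 rose, 1 fell and 10 did not pass (28 and 1 adjusted over the list alone), with a median log2 fold change of 1.31 (camera adjusted p = 3.43e-29, and 0.0391 with an estimated correlation). The antiviral enzymes OASL and OAS2 rose 5.88-fold (to 261 ± 16.9 CPM) and 8.23-fold, together with MX2 (3.05 ± 0.51) and IFI44L (2.73 ± 0.20) (adjusted p of at most 5.04e-05). The median of the list was 1.22 and 1.29 above the WT mean in the 2 Kashlid libraries, and 0.04 above it in each SUN2KO library. Genes for NF-kB cytokines and chemokines rose as well: of 23, 12 rose, 3 fell and 8 did not pass (13 and 3 adjusted over the list alone), median 0.46 (camera adjusted p = 0.00194, and 0.452 with an estimated correlation). Beside PTGS2, they included CXCL10 (2.32 ± 0.46), CXCL8 (1.73 ± 0.35) and IL1A (1.68 ± 0.36) with adjusted p = 0.000343, 0.000458 and 0.000774; CXCL8 was at 0.43 (adjusted p = 0.058) without Kashlid replicate 1. In the immediate early list (24 measured), 9 rose, 2 fell and 13 did not pass (9 and 3 adjusted over the list alone), median 0.23 (camera adjusted p = 0.0139, and 0.492 with an estimated correlation). DUSP5 (1.47 ± 0.21), MYC (1.08 ± 0.06) and IER3 (0.87 ± 0.08) rose next to EGR1.

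Contractile and adhesion genes fell. Of 23 SRF/MRTF targets, 3 rose, 17 fell and 3 did not pass (3 and 17 adjusted over the list alone), median -0.30 (camera adjusted p = 2.09e-06, and 0.0943 with an estimated correlation). The myosin light chain MYL9 fell 2.75-fold, and CALD1 (-0.88 ± 0.05), ACTA2 (-0.76 ± 0.24) and TGFB1I1 (-0.72 ± 0.15) fell too (adjusted p of at most 0.0142). Among 32 integrin and focal adhesion genes, 2 rose, 19 fell and 11 did not pass (2 and 19 adjusted over the list alone), median -0.30 (camera adjusted p = 1.69e-06, and 0.0634 with an estimated correlation). ITGA1 (-1.40 ± 0.06), ITGB1 (-0.99 ± 0.05), CAV1 (-0.88 ± 0.07) and BCAR1 (-0.77 ± 0.07) were among those that changed (adjusted p of at most 1.91e-08). For YAP/TAZ targets (22 measured), 2 rose, 9 fell and 11 did not pass (2 and 9 adjusted over the list alone), median -0.19 (camera adjusted p = 0.0116, and 0.281 with an estimated correlation). CTGF (-1.35 ± 0.26), CYR61 (-0.83 ± 0.12), CRIM1 (-0.71 ± 0.07) and DOCK5 (-0.54 ± 0.06) were among those that changed (adjusted p of at most 0.000226). In the LINC and nuclear envelope list (26 measured), 7 rose, 6 fell and 13 did not pass (7 and 6 adjusted over the list alone), median -0.01 (camera adjusted p = 0.866). SYNE3 (1.996 ± 0.26) and SYNE2 (0.34 ± 0.06) rose and TMEM201 (-0.54 ± 0.09) fell (adjusted p = 2.34e-06, 6.13e-05 and 4.52e-05).

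Sterol and cell cycle genes fell. All 19 changed genes of the cholesterol synthesis list were lower (24 measured, 5 not passing, 0 and 19 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 7.35e-14, and 0.0943 with an estimated correlation). The enzymes SQLE (-1.50 ± 0.10), IDI1 (-1.32 ± 0.09), LSS (-1.22 ± 0.08) and MSMO1 (-1.17 ± 0.08) fell most (adjusted p of at most 3.48e-10). Of 45 proliferation genes, 3 rose, 31 fell and 11 did not pass (3 and 32 adjusted over the list alone), median -0.27 (camera adjusted p = 9.18e-07, and 0.138 with an estimated correlation). E2F8 (-0.77 ± 0.12), CCNA2 (-0.67 ± 0.06), CDCA8 (-0.67 ± 0.08) and KIF20A (-0.59 ± 0.06) were among those that changed (adjusted p of at most 2.05e-05). Among 18 heat shock genes, 1 rose, 11 fell and 6 did not pass (1 and 11 adjusted over the list alone), median -0.20 (camera adjusted p = 0.0216, and 0.517 with an estimated correlation). HSPA4L (-0.68 ± 0.07), DNAJA1 (-0.53 ± 0.06) and DNAJB1 (-0.40 ± 0.07) were among those that changed. For 28 p53 and DNA damage genes, 3 rose, 13 fell and 12 did not pass (3 and 14 adjusted over the list alone), median -0.21 (camera adjusted p = 0.0189, and 0.136 with an estimated correlation). GDF15 (-1.64 ± 0.14) and PLK2 (-0.77 ± 0.09) fell and PMAIP1 (0.61 ± 0.12) rose. TNFRSF10C had 3 counts in Kashlid and 21 in WT, a ratio of 6.98 with a 95% counting interval of 2.09 to 36.6.

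Epithelial genes rose again. Of 28 measured, 17 rose, 5 fell and 6 did not pass (19 and 5 adjusted over the list alone), median 0.32 (camera adjusted p = 0.0035, and 0.0943 with an estimated correlation). CLDN7 (1.86 ± 0.12), SPINT1 (1.77 ± 0.17) and KRT15 (1.35 ± 0.27) were highest (adjusted p of at most 0.000359). Mesenchymal and EMT factors (22 measured) gave a median of -0.21: 2 rose, 9 fell and 11 did not pass (3 and 10 adjusted over the list alone) (camera adjusted p = 0.0648). NRP2 (2.06 ± 0.09) rose, and PDGFRB (-1.90 ± 0.15), TGFBI (-1.18 ± 0.07) and TWIST1 (-0.79 ± 0.22) fell. Among 37 collagens and matrix glycoproteins, 11 rose, 18 fell and 8 did not pass (12 and 18 adjusted over the list alone), median -0.17 (camera adjusted p = 0.00923, and 0.113 with an estimated correlation). THBS1 (-2.07 ± 0.11) and COL3A1 (-1.92 ± 0.44) fell and COL8A1 (1.97 ± 0.26) rose (adjusted p = 9.78e-12, 0.00133 and 2.54e-06), while COL13A1 had 2 counts in WT and 35 in Kashlid, a ratio of 17.5 (95% counting interval 4.51 to 151). In the matrix protease list (33 measured), 8 rose, 10 fell and 15 did not pass (8 and 10 adjusted over the list alone), median -0.05 (camera adjusted p = 0.121). MMP16 had 0 counts in Kashlid, at least 85.1-fold lower than in WT, SERPINE2 (-1.07 ± 0.07) fell and ADAM8 (1.29 ± 0.20) and ADAM12 (0.92 ± 0.11) rose.

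Of 34 hypoxia and glycolysis genes, 11 rose, 9 fell and 14 did not pass (11 and 10 adjusted over the list alone), median 0.03 (camera adjusted p = 0.262). ANGPTL4 (1.51 ± 0.23), MXI1 (1.28 ± 0.10) and DDIT4 (0.91 ± 0.06) were higher and ANKRD37 (-1.06 ± 0.38) was lower. The unfolded protein and ATF4 list (32 measured) split as follows: 4 rose, 10 fell and 18 did not pass (4 and 10 adjusted over the list alone), median -0.03 (camera adjusted p = 0.181). The stress regulator NUPR1 (-0.79 ± 0.28) and the amino acid transporter subunits SLC3A2 (-0.79 ± 0.08) and SLC7A5 (-0.76 ± 0.06) were among those that fell. Ribosomal protein genes had a median of 0.18, with 34 higher, 3 lower and 12 not passing (35 and 3 adjusted over the list alone) of 49 (camera adjusted p = 2.67e-07, and 0.255 with an estimated correlation). RPS18 rose by 0.53 ± 0.04 and RPL38 by 0.52 ± 0.05. Luminal markers (11 measured) had a median of 0.10 and a mean of -0.41: 5 rose, 2 fell and 4 did not pass (5 and 2 adjusted over the list alone) (camera adjusted p = 0.362). AGR2 (2.58 ± 0.38), MLPH (-1.16 ± 0.24) and TFF1 (0.98 ± 0.31) were among those that changed. HEK293-type markers (7 measured) had 1 gene higher, LIN28B with 17 counts against 0 in WT (at least 5.68-fold), 2 lower, TUBB2B (-0.95 ± 0.17) and INA (-0.72 ± 0.16), and 4 not passing (1 and 2 adjusted over the list alone; camera adjusted p = 0.802).

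In Kashlid the call of a list ended without 1 library for heat shock genes (camera adjusted p = 0.137 without WT replicate 1 and 0.102 without Kashlid replicate 1), immediate early genes (0.302 without Kashlid replicate 1), p53 genes (0.066 without Kashlid replicate 2), and with no filter for collagens (0.0981). Named genes that lost their call, with adjusted p in brackets, were TFF1 (0.0516 without WT replicate 1, 0.0671 without WT replicate 2 and 0.0715 without Kashlid replicate 1) and ADAM12 (0.297 with the window offset). Others were ACTA2 (0.063 in DESeq2 and 0.0867 without Kashlid replicate 2), ANKRD37 (0.0958 in DESeq2, 0.162 without WT replicate 2 and 0.324 with the window offset) and NUPR1 (0.217 in DESeq2 and 0.372 without Kashlid replicate 2). TNFRSF10C lost it in DESeq2 (0.472) and without either WT library (0.108 and 0.128) or Kashlid replicate 1 (0.21), where it was at -1.75. NUPR1 was at -1.59 without Kashlid replicate 1, and COL13A1 (0 and 2 WT counts) at 3.09 without WT replicate 1.

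Comparing LBD with WT asks what the truncation meant to detach SUN2 from the lamins does. The picture was close to that of Kashlid. AKR1C2 rose 22.7-fold to 24.6 ± 0.423 CPM (SD, n = 2; its paralogs may share reads), COL5A3 rose 21.3-fold to 12.5 ± 0.127 CPM, and PTGS2 rose 7.81-fold to 284 ± 33.4 CPM. OAS2, an interferon-induced antiviral enzyme (chromosome 12, 113416274 to 113449528), rose 8.97-fold from 2.05 ± 0.887 to 18.3 ± 1.47 CPM. TUSC3 fell 23.5-fold to 2.50 ± 0.316 CPM, and CGA, the common subunit of the glycoprotein hormones (chromosome 6, 87795216 to 87804865), fell 7.54-fold to 1.70 ± 0.459 CPM.

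Further increases were found in SRPX2 (3.36 ± 0.19), SYTL4 (3.33 ± 0.18), RNF125 (3.31 ± 0.25) and NOTCH3 (3.06 ± 0.13), TC2N (3.004 ± 0.16) and GPR97 (2.92 ± 0.25), with adjusted p of at most 1.09e-08. Further decreases were found in PZP (-3.43 ± 0.41), MYLK3 (-2.78 ± 0.23), KATNAL2 (-2.76 ± 0.20), QPRT (-2.60 ± 0.19), NEXN (-2.56 ± 0.15), GPNMB (-2.48 ± 0.21) and OLFM1 (-2.31 ± 0.18), with adjusted p of at most 1.06e-06. STC1 was at 11.2 ± 10.8 CPM, with a wide spread between the 2 libraries (-2.20 ± 0.35, adjusted p = 3.59e-05, and adjusted p = 0.11 in DESeq2). It was at -1.43 without LBD replicate 1 and -3.84 without LBD replicate 2. PZP was at -2.75 without WT replicate 1 and MYLK3 at -3.38 without LBD replicate 1. In total 5611 genes changed, 2670 higher and 2941 lower, 813 by at least 2-fold, and DESeq2 called 4460. With library size only, 3059 were higher and 2589 lower. The authors' deposited results passed 3883 genes, of which 3865 were also called here, all in the same direction.

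The interferon list stood highest in LBD too. Of 39 measured genes, 28 rose, 1 fell and 10 did not pass (28 and 1 adjusted over the list alone), median 1.26 (camera adjusted p = 3.96e-35, and 0.0272 with an estimated correlation). OASL rose 6.39-fold to 284 ± 29.3 CPM, ISG15 rose 5.73-fold to 180.3 ± 40.8 CPM, and MX2 rose by 2.98 ± 0.51 (adjusted p of at most 8.65e-05). The list's median above the WT mean was 1.17 and 1.32 in the 2 LBD libraries. NF-kB cytokines and chemokines (23 measured) followed: 14 rose, 3 fell and 6 did not pass (15 and 3 adjusted over the list alone), median 0.45 (camera adjusted p = 0.000645, and 0.497 with an estimated correlation). CCL5 rose 2.68-fold from 16.4 ± 1.32 to 43.9 ± 8.30 CPM, and CXCL10 (2.09 ± 0.47) and IL1B (1.75 ± 0.38) rose too (adjusted p of at most 0.00135). Immediate early genes (24 measured) were divided, as 8 rose, 6 fell and 10 did not pass (8 and 6 adjusted over the list alone), median 0.06 (camera adjusted p = 0.183). EGR1 (1.78 ± 0.26), DUSP5 (1.27 ± 0.22), IER3 (0.90 ± 0.08) and MYC (0.79 ± 0.06) were higher. Epithelial genes rose: of 28, 18 rose, 4 fell and 6 did not pass (18 and 4 adjusted over the list alone), median 0.45 (camera adjusted p = 1.31e-06, and 0.044 with an estimated correlation). KRT15 (1.82 ± 0.26), SPINT1 (1.76 ± 0.17), CLDN7 (1.51 ± 0.12) and KRT17 (1.14 ± 0.07) were the largest (adjusted p of at most 1.07e-05).

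Sterol and contractile genes fell in LBD too. Of 24 cholesterol synthesis genes, 0 rose, 21 fell and 3 did not pass (0 and 21 adjusted over the list alone), median -0.51 (camera adjusted p = 1.37e-18, and 0.0741 with an estimated correlation). SQLE (-1.44 ± 0.10), LSS (-1.41 ± 0.08), IDI1 (-1.32 ± 0.09) and MSMO1 (-1.17 ± 0.08) were among those that changed (adjusted p of at most 4.74e-10). Among 23 SRF/MRTF targets, 2 rose, 14 fell and 7 did not pass (4 and 15 adjusted over the list alone), median -0.20 (camera adjusted p = 0.000199, and 0.154 with an estimated correlation). MYL9 (-1.27 ± 0.09), ACTA2 (-0.99 ± 0.25), CALD1 (-0.98 ± 0.05) and TGFB1I1 (-0.89 ± 0.15) were among those that changed (adjusted p of at most 0.00296). The 22 measured YAP/TAZ targets had a median of -0.27: 3 rose, 11 fell and 8 did not pass (3 and 12 adjusted over the list alone) (camera adjusted p = 0.0245, and 0.298 with an estimated correlation). CTGF (-1.29 ± 0.26), CRIM1 (-0.75 ± 0.07) and CYR61 (-0.60 ± 0.11) fell and the ectonucleotidase gene NT5E (0.95 ± 0.11) rose (adjusted p of at most 0.00039). In the integrin list (32 measured), 5 rose, 17 fell and 10 did not pass (5 and 17 adjusted over the list alone), median -0.19 (camera adjusted p = 0.0114, and 0.165 with an estimated correlation). ITGA1 (-1.05 ± 0.06) and ITGB1 (-0.81 ± 0.05) fell and ITGA2 (1.03 ± 0.08) and ITGA5 (0.74 ± 0.06) rose. The LINC and nuclear envelope list (26 measured) had 5 higher, 6 lower and 15 not passing (5 and 6 adjusted over the list alone), median -0.03 (camera adjusted p = 0.925). SYNE3 (1.76 ± 0.26) and TMEM43 (0.49 ± 0.05) were higher.

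Proliferation genes fell as a group: of 45, 3 rose, 24 fell and 18 did not pass (3 and 24 adjusted over the list alone), median -0.14 (camera adjusted p = 0.000468, and 0.257 with an estimated correlation). E2F8 (-0.69 ± 0.12), CENPE (-0.64 ± 0.07) and E2F1 (-0.63 ± 0.07) were among those that changed (adjusted p of at most 7.07e-05). In the p53 and DNA damage list (28 measured), 2 rose, 11 fell and 15 did not pass (2 and 13 adjusted over the list alone), median -0.19 (camera adjusted p = 0.0471, and 0.194 with an estimated correlation). GDF15 (-1.40 ± 0.14) and RRM2B (-0.57 ± 0.08) were lower. For the unfolded protein and ATF4 list (32 measured), 3 rose, 10 fell and 19 did not pass (3 and 10 adjusted over the list alone), median -0.16 (camera adjusted p = 0.0471, and 0.257 with an estimated correlation). NUPR1 (-1.61 ± 0.30), SLC7A5 (-0.78 ± 0.06) and SLC3A2 (-0.78 ± 0.08) were lower. Collagens and matrix glycoproteins (37 measured) included 10 higher, 15 lower and 12 not passing (11 and 17 adjusted over the list alone), median -0.10 (camera adjusted p = 0.0471, and 0.194 with an estimated correlation). THBS1 (-1.73 ± 0.11) fell, COL8A1 (1.80 ± 0.26) rose, and COL13A1 had 24 counts against 2 in WT, a ratio of 12.1 (95% counting interval 3.02 to 106). Of 22 mesenchymal and EMT factors, 5 rose, 8 fell and 9 did not pass (5 and 8 adjusted over the list alone), median -0.21 (camera adjusted p = 0.236). NRP2 (2.15 ± 0.09) and CDH4 (1.04 ± 0.37) were higher and PDGFRB (-1.42 ± 0.14) and TGFBI (-0.95 ± 0.07) were lower.

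Of 33 matrix protease genes, 10 rose, 8 fell and 15 did not pass (10 and 8 adjusted over the list alone), median 0.07 and mean -0.18 (camera adjusted p = 0.989). ADAM12 (1.35 ± 0.11) and ADAM8 (1.34 ± 0.20) rose and ADAMTS1 (-1.07 ± 0.08) fell, and MMP16 had 1 count in LBD and 256 in WT, a ratio of 253 (95% counting interval 45 to 10000). Of 34 hypoxia and glycolysis genes, 12 rose, 6 fell and 16 did not pass (12 and 6 adjusted over the list alone), median 0.02 (camera adjusted p = 0.138). ANGPTL4 (1.72 ± 0.23) and MXI1 (1.03 ± 0.10) were higher and ANKRD37 (-1.16 ± 0.39) was lower. Of 18 heat shock genes, 2 rose, 6 fell and 10 did not pass (2 and 6 adjusted over the list alone), median -0.02 (camera adjusted p = 0.661). HSPA4L (-0.66 ± 0.07) and DNAJA1 (-0.32 ± 0.06) were lower. Ribosomal protein genes (49 measured) had 17 higher, 8 lower and 24 not passing (18 and 8 adjusted over the list alone), median 0.04 (camera adjusted p = 0.179), RPS13 by 0.37 ± 0.05 and RPS20 by -0.55 ± 0.05. Luminal markers (11 measured) had 6 higher, 2 lower and 3 not passing (6 and 2 adjusted over the list alone), median 0.44 (camera adjusted p = 0.0761). AGR2 (2.46 ± 0.39) and TFF1 (1.54 ± 0.29) were higher and MLPH (-1.38 ± 0.25) was lower. HEK293-type markers (7 measured) had 1 higher, 1 lower and 5 not passing (1 and 1 adjusted over the list alone), median -0.04 and mean 0.77 (camera adjusted p = 0.989). LIN28B had 23 counts against 0 in WT, at least 7.76-fold higher, and TUBB2B (-0.82 ± 0.17) fell.

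In LBD the list calls near the threshold ended under some settings: unfolded protein response, p53 and collagen lists reached camera adjusted p = 0.0678 without LBD replicate 1 and 0.0935, 0.0549 and 0.0549 without WT replicate 2. The integrin list reached 0.0678 without LBD replicate 1, and the YAP/TAZ list 0.0805 with a stricter filter. With library size only, 8 lists were called, and the unfolded protein response, p53 and collagen lists were each at 0.0574. DNAJA1 lost its call with the window offset (adjusted p = 0.151). The call also ended, with adjusted p in brackets, for CDH4 (0.0935 in DESeq2 and 0.202 without LBD replicate 2) and ANKRD37 (0.0784 in DESeq2, 0.241 without LBD replicate 1 and 0.314 with the window offset). Without LBD replicate 2, ANKRD37 was at -1.80 and ANGPTL4 at 1.06. COL13A1 (0 and 2 counts in WT replicates 1 and 2) lost its call without WT replicate 1, at 2.56.

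**Figure D3:**
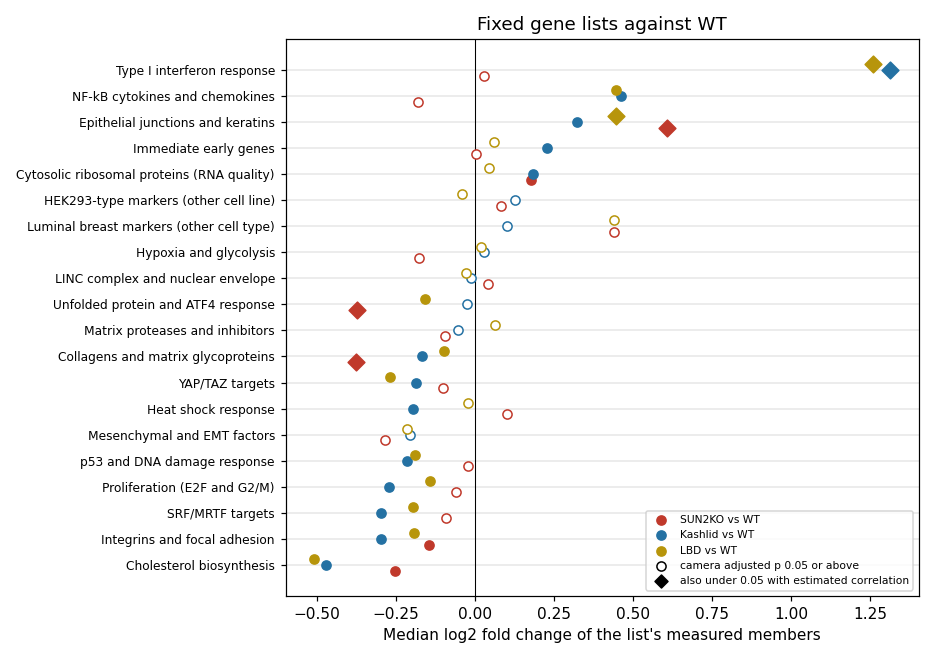
Median log2 fold change of the measured members of the fixed gene lists shown, against WT, 1 colour per comparison. Filled symbols have a camera adjusted p under 0.05 and diamonds also with an estimated correlation. The interferon list stands at 1.31 in Kashlid and 1.26 in LBD and at 0.03 in SUN2KO, and the cholesterol list lies below 0 in all 3.

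The 3 lines shared many of their changes against WT. Of 8103 genes changed in any of the 3 comparisons, 1442 were higher and 1797 lower in all 3, where independent lists would share 102 and 128. Across 14016 genes the log2 fold changes correlated at r = 0.749 between SUN2KO and Kashlid, 0.751 between SUN2KO and LBD, and 0.903 between Kashlid and LBD (genes are not independent replicates). Unchanged groups and shared controls, both simulated, gave mean r of 0.505, 0.4997 and 0.498 over 20 simulations. The covariance was 0.363, 0.349 and 0.479, where the simulated values were 0.0244, 0.0241 and 0.0245. SUN2KO and Kashlid had 1744 genes higher in both and 2006 lower in both (534 and 609 for independent lists). For SUN2KO and LBD these were 1639 and 1994 (468 and 563), and for Kashlid and LBD 2164 and 2446 (580 and 668). The 2 WT libraries cannot be split into parts of 2, so part of the excess may come from the shared controls.

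**Figure D4:**
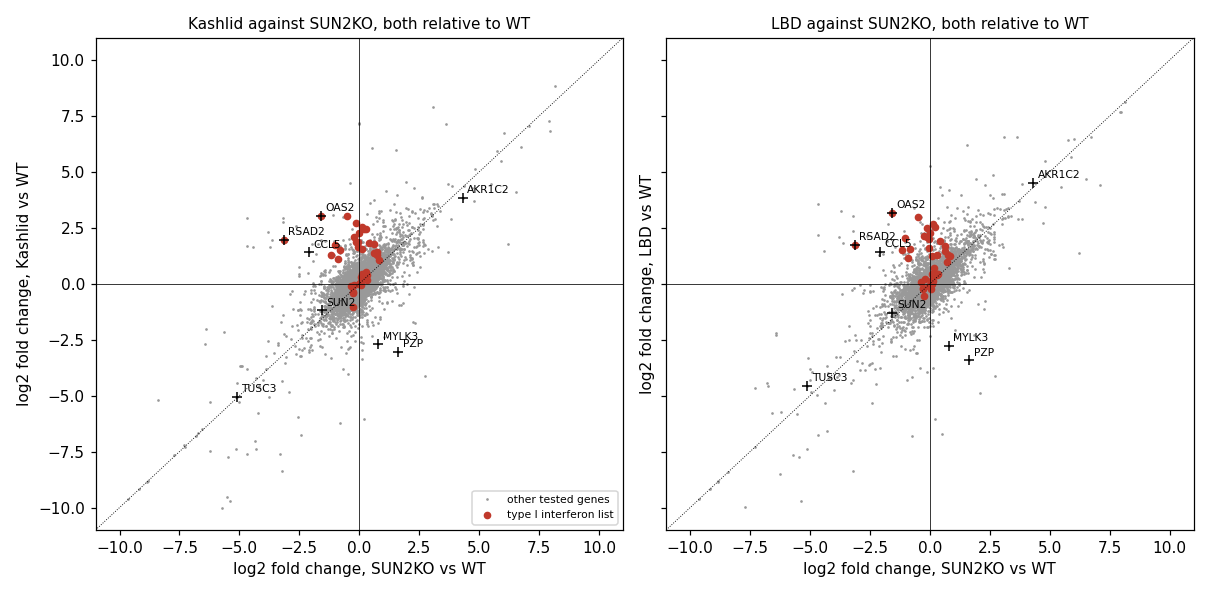
Log2 fold changes against WT of 14016 genes in Kashlid (left) and LBD (right) plotted against those in SUN2KO, with the interferon list in red, 8 named genes marked and a dotted line of equal change. The cloud of genes runs along the line (r = 0.749 and 0.751), whereas OAS2, RSAD2 and CCL5 lie in the upper left and MYLK3 and PZP in the lower right.

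Comparing each truncation with SUN2KO asks how far the truncation lines differ from the knockout line. RSAD2 (chromosome 2, 7017796 to 7038363) was 34.7-fold higher in Kashlid and 29.5-fold higher in LBD, at 9.61 ± 0.643 and 8.17 ± 0.391 CPM against 0.269 ± 0.0749 in SUN2KO (SD, n = 2). OAS2 was higher by 4.62 ± 0.24 and 4.75 ± 0.24 on the log2 scale, and CCL5 by 3.50 ± 0.14 and 3.51 ± 0.14. PZP, a protease inhibitor of the alpha-2-macroglobulin family (chromosome 12, 9301436 to 9360966), was 25.3-fold lower in Kashlid and 33.3-fold lower in LBD, and MYLK3 (chromosome 16, 46736194 to 46782221) was 11.3-fold and 11.8-fold lower. DKK1 was 6.39-fold lower in Kashlid and CGA 3.65-fold lower in LBD. The adjusted p of these values was at most 2.08e-05. STC1 was higher in LBD by 4.21 ± 0.68 (adjusted p = 0.000161), with values from 2.56 without LBD replicate 2 to 6.03 without SUN2KO replicate 2. MYLK3 in LBD was at -4.18 without LBD replicate 1. RPPH1 and RMRP, the other large increases of Kashlid, rested on its replicate 2, without which their values were -0.39 (adjusted p = 0.907) and -0.41 (adjusted p = 0.893).

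Kashlid differed from SUN2KO in 2529 genes, 1250 higher and 1279 lower, and LBD in 1890, 938 higher and 952 lower. With library size only, in place of TMM factors, the counts were 1574 higher and 996 lower for Kashlid, and 1128 and 718 for LBD. Of the 5137 genes changed in SUN2KO, 3913 (76.2%) had no call against SUN2KO in Kashlid and 4124 (80.3%) had none in LBD. Leaving out 1 library lowered the count to 1186 for Kashlid without SUN2KO replicate 1, and to 1622 without SUN2KO replicate 2. For LBD it fell to 885 and 1097 without these and to 884 without LBD replicate 2.

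List tests for these comparisons were added after seeing the data. The interferon list was higher in both truncation lines: of 39 genes, 25 were higher, 1 lower and 13 did not pass (26 and 1 adjusted over the list alone) in Kashlid, median 0.77 (camera adjusted p = 2.98e-67, and 0.00686 with an estimated correlation). In LBD 24 were higher, 1 lower and 14 did not pass (24 and 1 adjusted over the list alone), median 0.82 (camera adjusted p = 7.82e-81, and 0.00472 with an estimated correlation). Beside RSAD2 and OAS2, MX2 (3.56 ± 0.53) and IFI44L (2.86 ± 0.20) were higher in Kashlid and MX2 (3.48 ± 0.54) and SAMD9L (3.08 ± 0.45) in LBD. NF-kB cytokines and chemokines (23 measured) had medians of 0.39 and 0.45: 9 were higher, 0 lower and 14 did not pass (9 and 0 adjusted over the list alone) in Kashlid (camera adjusted p = 1.58e-12, and 0.139 with an estimated correlation). In LBD 11 were higher, 0 lower and 12 did not pass (11 and 0 adjusted over the list alone) (camera adjusted p = 6.57e-15, and 0.191 with an estimated correlation). PTGS2 was higher by 2.81 ± 0.11 and 2.63 ± 0.11, CXCL8 by 2.63 ± 0.38 and 2.004 ± 0.40, and CXCL10 had 81 and 68 counts against 1 in SUN2KO, ratios of 87.5 and 74.1 with 95% counting intervals of 15.3 to 3500 and 12.9 to 2970. CXCL8 in Kashlid was at 1.33 (adjusted p = 9.24e-06) without Kashlid replicate 1 and 3.31 without Kashlid replicate 2. CXCL8 in LBD was at 1.73 (adjusted p = 0.0539) without SUN2KO replicate 2.

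The unfolded protein and ATF4, matrix and hypoxia lists had medians above 0 in both truncation lines against SUN2KO. For the unfolded protein and ATF4 list (32 measured), 16 were higher, 1 lower and 15 did not pass (18 and 2 adjusted over the list alone) in Kashlid, median 0.26 (camera adjusted p = 5.76e-11, and 0.0376 with an estimated correlation). In LBD 13 were higher, 2 lower and 17 did not pass (14 and 4 adjusted over the list alone), median 0.16 (camera adjusted p = 2.38e-09, and 0.0485 with an estimated correlation). HSPA5 was higher by 0.73 ± 0.05 and 0.79 ± 0.05, HERPUD1 by 0.81 ± 0.06 and 0.78 ± 0.06, and PDIA4 by 0.64 ± 0.05 and 0.78 ± 0.05. ASNS was higher in Kashlid by 0.68 ± 0.20 and NUPR1 changed by -0.97 ± 0.32 in LBD. For collagens and matrix glycoproteins (37 measured), 18 were higher, 9 lower and 10 did not pass (19 and 11 adjusted over the list alone) in Kashlid, median 0.16 (camera adjusted p = 0.00431, and 0.0998 with an estimated correlation). In LBD 16 were higher, 6 lower and 15 did not pass (19 and 6 adjusted over the list alone), median 0.19 (camera adjusted p = 2.05e-05, and 0.0485 with an estimated correlation). FN1 was higher by 1.30 ± 0.05 and 1.48 ± 0.05, COL8A1 by 2.65 ± 0.27 and 2.48 ± 0.28, and DCN by 1.19 ± 0.13 and 1.22 ± 0.13, and COL13A1 in Kashlid by 2.39 ± 0.63. Hypoxia and glycolysis genes (34 measured) had medians of 0.21 and 0.16: 14 were higher, 5 lower and 15 did not pass (14 and 6 adjusted over the list alone) in Kashlid (camera adjusted p = 0.000658, and 0.602 with an estimated correlation). In LBD 8 were higher, 1 lower and 25 did not pass (15 and 1 adjusted over the list alone) (camera adjusted p = 2.39e-05, and 0.44 with an estimated correlation). ANGPTL4 was higher by 1.77 ± 0.23 and 1.99 ± 0.23, NDRG1 by 1.13 ± 0.25 and 1.20 ± 0.25, the glucose transporter SLC2A3 by 0.92 ± 0.11 and 0.79 ± 0.11, and CA9 in Kashlid by 1.06 ± 0.33. The hypoxia list was higher in replicate 2 than in replicate 1 in every group, by a median of 0.112 in WT, 0.052 in SUN2KO, 0.170 in Kashlid and 0.247 in LBD. Its median against SUN2KO was 0.059 without Kashlid replicate 2 (camera adjusted p = 0.0497) and 0.027 without LBD replicate 2 (0.0643), so its size rested on these libraries. In Kashlid the call of a gene ended, with adjusted p in brackets, for ASNS (0.305 in DESeq2 and 0.839 without Kashlid replicate 1), COL13A1 (0.0596 in DESeq2 and 0.102 without SUN2KO replicate 2), NDRG1 (0.159 in DESeq2 and 0.0985 without SUN2KO replicate 1) and CA9 (0.37 in DESeq2 and 0.368 without SUN2KO replicate 1). In LBD it ended for NUPR1 (0.295 in DESeq2 and 0.234 without LBD replicate 2) and NDRG1 (0.15 in DESeq2 and 0.192 without LBD replicate 2). Without LBD replicate 2, NDRG1 in LBD was at 0.50 and ANGPTL4 at 1.32, and ASNS in Kashlid was at 0.056 without Kashlid replicate 1.

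The cholesterol, contractile and cell cycle lists had medians under 0 in both truncation lines against SUN2KO. Of 24 cholesterol synthesis genes, 1 was higher, 15 lower and 8 did not pass (1 and 15 adjusted over the list alone) in Kashlid, median -0.33 (camera adjusted p = 4.22e-10, and 0.108 with an estimated correlation). In LBD 0 were higher, 16 lower and 8 did not pass (1 and 21 adjusted over the list alone), median -0.31 (camera adjusted p = 6.57e-15, and 0.0891 with an estimated correlation). SQLE changed by -0.88 ± 0.10 and -0.83 ± 0.10, and MVK in LBD by -0.89 ± 0.14. Of 23 SRF/MRTF targets, 0 were higher, 15 lower and 8 did not pass (0 and 15 adjusted over the list alone) in Kashlid, median -0.21 (camera adjusted p = 1.35e-07, and 0.0702 with an estimated correlation). In LBD 0 were higher, 9 lower and 14 did not pass (0 and 9 adjusted over the list alone), median -0.15 (camera adjusted p = 0.00017, and 0.136 with an estimated correlation). MYL9 changed by -1.08 ± 0.09 and -0.89 ± 0.09, and ACTG2 in Kashlid by -1.66 ± 0.34. Proliferation genes (45 measured) had medians of -0.20 and -0.14: 2 were higher, 23 lower and 20 did not pass (2 and 28 adjusted over the list alone) in Kashlid (camera adjusted p = 3.01e-10, and 0.0998 with an estimated correlation). In LBD 1 was higher, 14 lower and 30 did not pass (1 and 21 adjusted over the list alone) (camera adjusted p = 4.82e-05, and 0.195 with an estimated correlation). Heat shock genes (18 measured) showed 0 higher, 11 lower and 7 not passing (0 and 13 adjusted over the list alone) in Kashlid (camera adjusted p = 6.32e-06, and 0.31 with an estimated correlation). LBD had 0 higher, 3 lower and 15 not passing (0 and 5 adjusted over the list alone) (camera adjusted p = 0.0991).

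Epithelial genes, with 28 measured, were lower in Kashlid than in SUN2KO, with 2 higher, 10 lower and 16 not passing (3 and 11 adjusted over the list alone) (camera adjusted p = 0.000367, and 0.0702 with an estimated correlation). KRT7 was lower (-0.86 ± 0.06). In LBD there were 3 higher, 8 lower and 17 not passing (4 and 9 adjusted over the list alone) (camera adjusted p = 0.251). Immediate early genes (24 measured) showed 11 higher, 1 lower and 12 not passing (12 and 2 adjusted over the list alone) in Kashlid (camera adjusted p = 0.000193, and 0.356 with an estimated correlation). LBD had 6 higher, 3 lower and 15 not passing (9 and 3 adjusted over the list alone) (camera adjusted p = 0.0854), where EGR1 changed by -1.22 ± 0.19. Of 33 matrix protease genes, 11 were higher, 7 lower and 15 did not pass (12 and 10 adjusted over the list alone) in Kashlid (camera adjusted p = 0.852). In LBD 10 were higher, 2 lower and 21 did not pass (10 and 4 adjusted over the list alone) (camera adjusted p = 0.00386, and 0.195 with an estimated correlation). MMP24 changed by -1.29 ± 0.18 and -1.27 ± 0.18. Integrin genes (32 measured) had 4 higher, 10 lower and 18 not passing (4 and 13 adjusted over the list alone) in Kashlid (camera adjusted p = 0.0327, and 0.139 with an estimated correlation). LBD had 5 higher, 4 lower and 23 not passing (7 and 7 adjusted over the list alone) (camera adjusted p = 0.164), and ITGA2 was higher by 1.20 ± 0.08 and 1.53 ± 0.08. YAP/TAZ targets (22 measured) had 1 higher, 5 lower and 16 not passing (2 and 8 adjusted over the list alone) in Kashlid (camera adjusted p = 0.0359, and 0.334 with an estimated correlation). LBD had 1 higher, 6 lower and 15 not passing (2 and 9 adjusted over the list alone) (camera adjusted p = 0.0993). NT5E changed by 0.76 ± 0.12 and 1.46 ± 0.12. CTGF changed by -0.79 ± 0.27 in Kashlid, a call that ended in other settings: CTGF (0.132 in DESeq2 and 0.301 without Kashlid replicate 2). For p53 genes (28 measured) the counts were 3 higher and 9 lower in Kashlid (camera adjusted p = 0.0177, and 0.108 with an estimated correlation) and 2 higher and 8 lower in LBD (camera adjusted p = 0.0854; 3 and 10, and 5 and 8, adjusted over the list alone). PLK2 changed by -1.13 ± 0.08 and -0.78 ± 0.08. Ribosomal protein genes (49 measured) had 2 higher, 1 lower and 46 not passing (1 and 0 adjusted over the list alone) in Kashlid (camera adjusted p = 0.658). LBD had 0 higher, 26 lower and 23 not passing (0 and 35 adjusted over the list alone), median -0.13 (camera adjusted p = 2.99e-09, and 0.195 with an estimated correlation). The LINC, EMT, luminal and HEK293-type lists had camera adjusted p between 0.29 and 0.88 in LBD and between 0.489 and 0.735 in Kashlid. Without 1 library, in Kashlid, the YAP/TAZ, integrin and p53 calls ended (0.467, 0.132 and 0.266 at most, without Kashlid replicate 2), as did the immediate early call (0.176 without Kashlid replicate 1).

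Comparing LBD with Kashlid asks whether the 2 truncation lines differ. They differed in 408 genes, 229 higher and 179 lower in LBD, and 16 of these by at least 2-fold. EGR1 was 2.51-fold lower in LBD (10.1 ± 0.0281 against 25.3 ± 9.87 CPM, SD, n = 2, adjusted p = 0.000613). SPINK6, a serine protease inhibitor (chromosome 5, 147582357 to 147594700), was 2.81-fold higher in LBD (adjusted p = 0.000103), and OLFM1 (0.93 ± 0.24) and NAV3 (0.93 ± 0.17) were also higher, while TXNIP (-0.98 ± 0.20) and DPM3 (-0.92 ± 0.18) were lower. The count was 129 without LBD replicate 1, 138 without LBD replicate 2 and 839 without Kashlid replicate 2, 129 with only the 2 groups compared and 775 with no filter. Of the 6 genes named here for their size, the call ended, with adjusted p in brackets, for OLFM1 (0.26 without LBD replicate 2), TXNIP (0.17 in DESeq2 and 0.142 without Kashlid replicate 1) and DPM3 (0.107 without LBD replicate 1). TXNIP was at -0.28 without Kashlid replicate 1.

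Ribosomal protein genes were slightly lower in LBD than in Kashlid. Of 49, 0 were higher, 21 lower and 28 did not pass (0 and 44 adjusted over the list alone), median -0.16 (camera adjusted p = 1.98e-24, and 0.121 with an estimated correlation). RPS12 (-0.26 ± 0.04), RPS18 (-0.24 ± 0.04), RPL32 (-0.23 ± 0.04) and RPL3 (-0.23 ± 0.04) were among those that changed (adjusted p of at most 0.00338). Adhesion genes were higher: of 32 in the integrin list, 9 were higher, 0 lower and 23 did not pass (14 and 1 adjusted over the list alone), median 0.16 (camera adjusted p = 5.63e-09, and 0.058 with an estimated correlation). ITGA1 (0.34 ± 0.06), ACTN1 (0.34 ± 0.05), ITGB4 (0.33 ± 0.08) and ITGA2 (0.33 ± 0.08) were among those that changed. Of 33 matrix protease genes, 8 were higher, 0 lower and 25 did not pass (9 and 1 adjusted over the list alone) (camera adjusted p = 3e-05, and 0.13 with an estimated correlation). SERPINE2 (0.53 ± 0.07) and ADAM12 (0.44 ± 0.10) were among those that changed. Of 28 epithelial genes, 7 were higher, 0 lower and 21 did not pass (8 and 1 adjusted over the list alone) (camera adjusted p = 8.09e-05, and 0.0897 with an estimated correlation). KRT81 (0.55 ± 0.06), KRT7 (0.43 ± 0.06) and KRT17 (0.36 ± 0.07) were among those that changed. Proliferation genes (45 measured) had 8 higher, 1 lower and 36 not passing (14 and 2 adjusted over the list alone) (camera adjusted p = 8.96e-05, and 0.248 with an estimated correlation), with CDCA8 (0.34 ± 0.08) and KIF20A (0.32 ± 0.06). Heat shock genes (18 measured) had 5 higher, 0 lower and 13 not passing (10 and 0 adjusted over the list alone) (camera adjusted p = 3.76e-06, and 0.37 with an estimated correlation), with the near-identical pair HSPA1A (0.38 ± 0.09) and HSPA1B (0.36 ± 0.08). For SRF/MRTF targets (23 measured), 3 were higher, 0 lower and 20 did not pass (7 and 1 adjusted over the list alone) (camera adjusted p = 0.00739, and 0.248 with an estimated correlation). ACTB (0.22 ± 0.04) was among those that changed. Immediate early genes (24 measured) had 0 higher, 4 lower and 20 not passing (0 and 6 adjusted over the list alone) (camera adjusted p = 0.00132, and 0.429 with an estimated correlation), with NR4A2 (-0.85 ± 0.15) and DUSP1 (-0.48 ± 0.13) beside EGR1. The camera adjusted p was 0.576 without Kashlid replicate 1 and 0.22 without LBD replicate 1.

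Luminal markers had 1 higher, 0 lower and 10 not passing (1 and 0 adjusted over the list alone) of 11 (camera adjusted p = 0.0338, and 0.248 with an estimated correlation), KRT8 by 0.25 ± 0.04. None of the 10 lists with a camera adjusted p under 0.05 kept it with an estimated correlation. The interferon list did not differ detectably, with 2 higher, 0 lower and 37 not passing (2 and 1 adjusted over the list alone) of 39, median 0.04 (camera adjusted p = 0.553), with OAS1 (0.36 ± 0.08) and OAS3 (0.28 ± 0.06) the 2 higher. The other lists described here had camera adjusted p between 0.0743 and 0.955. Most single genes named from these lists depended on 1 library. The call ended, with adjusted p in brackets, for RPS12 (0.0574 without LBD replicate 1), RPL32 (0.0606 without LBD replicate 1), ITGB4 (0.164 in DESeq2 and 0.414 without LBD replicate 2) and ITGA2 (0.115 in DESeq2 and 0.323 without LBD replicate 2). It ended as well for ADAM12 (0.235 without LBD replicate 2), KRT17 (0.119 without LBD replicate 2), CDCA8 (0.202 without LBD replicate 1), KIF20A (0.073 without LBD replicate 1), HSPA1A (0.203 in DESeq2 and 0.155 without Kashlid replicate 1) and HSPA1B (0.179 in DESeq2 and 0.143 without Kashlid replicate 1). Further cases were ACTB (0.0528 without LBD replicate 1), NR4A2 (0.0661 without LBD replicate 1), DUSP1 (0.301 in DESeq2 and 0.666 without Kashlid replicate 1), OAS1 (0.173 without LBD replicate 2) and OAS3 (0.0888 without LBD replicate 1). It held in DESeq2 and without any 1 library for RPS18, RPL3, ITGA1, ACTN1, SERPINE2, KRT81, KRT7 and KRT8.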

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

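Of the tests below, those of scaling, of 1 library for the interferon list, of the step that brought the truncations in, of the shared WT libraries, of regional shifts, of a shared origin, of the truncation itself for RMRP and RPPH1, and of histone genes were chosen after the result was seen. Some genes changed one way in SUN2KO and the other way in a truncation line against WT, with the difference itself passing edgeR's test between truncation and SUN2KO. There were 83 such genes for Kashlid (41 higher and 42 lower in Kashlid) and 91 for LBD (57 and 34). Among them, named after their values were seen, IFIT3 changed by -0.81 in SUN2KO, 1.51 in Kashlid and 1.57 in LBD against WT, DDX60 by -0.91, 1.11 and 1.15, and UNC13A by -1.05, 1.91 and 1.32. WISP2 went the other way, by 0.67, -1.50 and -1.12.

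The interferon list was higher in both truncation lines than in SUN2KO. Scaling between libraries is argued against by a list median of at least 0.768 over 3 scalings, and an effect of 1 library by a median of at least 0.552 without any 1 library. A response to the step that brought the truncations into the cells may explain the rise. It cannot be told apart from an effect of the truncations, because the 2 truncation lines differed by a list median of 0.044 and no library held that step without a truncation.

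Many changes against WT were shared by the 3 lines. Control noise of the simulated size as the whole cause is argued against by a covariance whose lowest ratio to the simulated one was 14.5. Regional shifts as the whole cause stay open: calls held without window medians (lowest 62.3%), but finer segments and genes outside windows stayed uncorrected. GC content as their cause is argued against by an SD of window medians, at lowest 0.186 without the GC trend. An origin shared by the 3 lines but not WT cells cannot be told apart from a common effect. This SD between truncation lines and SUN2KO, at most 0.0613, restates the shared pattern and no other value decides it.

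RMRP and RPPH1 were high in replicate 2 of the truncation lines. Replicate 2 was also the higher one in WT and SUN2KO for both genes, at 9 to 17 counts. Replicate-1 counts of the same lines cannot decide on the truncation alone, as the pattern was picked for them. They lay within the range of the WT and SUN2KO libraries (4 of 4). More SNORA and SNORD RNAs are argued against by a median log2 ratio of replicate 2 to 1 of at most 0.158 (130, mostly these). Others stay open. Poorer removal of RNAs without a poly(A) tail cannot be told apart from other causes, because the ratio over 43 histone genes, 0.348 in Kashlid and 0.073 in LBD, was small but in Kashlid the highest of the 4 groups, and TERC rose there from 10 to 37 counts and SCARNA2 from 6 to 34, while SNORA65 fell from 14 to 2.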

How the results depend on the processing

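The window offset and the lists against SUN2KO were chosen after seeing the data. Over 18 settings, 84 list results kept their side of the threshold in 1284 cases, gained a call in 36, lost one in 84 and reversed in 3. For 527 results of named genes these were 7661, 14, 450 and 7. With groups of 2, other splits could not be counted, and without 1 library the lone sample is assumed to vary like the other groups. Where a result below did not hold, the cause was not tested, except that a 2-fold limit passes fewer genes by construction.

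With a 2-fold limit, 630, 918 and 813 genes passed in SUN2KO, Kashlid and LBD against WT, 320 and 290 in Kashlid and LBD against SUN2KO, and 16 between LBD and Kashlid. With an estimated correlation camera called 3, 1 and 2 lists in SUN2KO, Kashlid and LBD against WT, and 0 between LBD and Kashlid, where the preset gave 10 and fry 3. In SUN2KO fry called 10. With no filter 775 genes differed between LBD and Kashlid, and the 3 correlations were 0.6045, 0.593 and 0.6625. A stricter filter gave 7 lists in LBD, and correlations with LBD of 0.7926 (SUN2KO) and 0.9392 (Kashlid). Library size only gave 8 lists in LBD and turned the majority upward in Kashlid and LBD against WT. With only the 2 groups compared, 129 genes differed between LBD and Kashlid, and correlations with SUN2KO were 0.8138 and 0.8149. The window offset turned MKI67 to -0.271, MCM10 to 0.116 and HSPB1 to 0.099 in SUN2KO, and MCM10 to 0.063 in LBD.

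Without 1 library, genes ranged from 3569 to 5694, 4720 to 6189 and 4014 to 6070 in SUN2KO, Kashlid and LBD against WT. They ranged from 1186 (without SUN2KO replicate 1) to 2469 in Kashlid and from 884 (without LBD replicate 2) to 2386 in LBD against SUN2KO, and from 129 (without LBD replicate 1) to 839 (without Kashlid replicate 2) between LBD and Kashlid. RMRP in Kashlid ranged from -0.769 to 5.482 against WT and from -0.406 to 6.15 against SUN2KO, and RPPH1 from -0.393 to 6.619 against SUN2KO, each lowest without Kashlid replicate 2. Between LBD and Kashlid, camera adjusted p ranged from 5.65e-19 to 0.576 for immediate early genes, 5.32e-07 to 0.995 for NF-kB genes and 1.31e-08 to 0.485 for hypoxia genes. The list direction turned without Kashlid replicate 1, Kashlid replicate 2 and LBD replicate 2 (6.22e-05) in that order. Correlations ranged from 0.6823 to 0.7818 (SUN2KO and Kashlid), 0.682 to 0.7886 (SUN2KO and LBD) and 0.8301 to 0.9058 (Kashlid and LBD).

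With a replicate block, 5412, 6457 and 5798 genes changed in SUN2KO, Kashlid and LBD against WT, 2787 and 2134 against SUN2KO, and 581 between LBD and Kashlid. In LBD 12 lists were called, as hypoxia genes passed (0.0296, and 2.32e-05 to 0.993 without 1 library). Libraries of the same number had deviations correlated between -0.00742 and 0.0844 over 6 pairs of groups, which was not taken as pairing.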

Other observations

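None of the values here was planned, and the genes were chosen after their values were seen. Besides RMRP and RPPH1, some small noncoding RNAs differed between the 2 Kashlid libraries: TERC, the RNA of telomerase, had 10 and 37 counts, and the Cajal body RNAs SCARNA2 and SCARNA10 had 6 and 34, and 5 and 22. Others went the other way, as SNORD50B had 9 and 1 counts and SNORA65 14 and 2. Of 130 such RNAs 13 were over 2-fold higher in replicate 2 in Kashlid, and 13 in SUN2KO. The first principal component of log2 CPM held 51.2% of the variance and the second 19.8%.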
